A study of Mus musculus with 12 samples.

How the data were processed

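RNA was measured in CD4 and CD8 T cells of young (8 weeks) and old (79 to 121 weeks) C57BL/6 mice on 12 Agilent 2-colour arrays of a mouse design. The spleen samples were naive cells, sorted by CD62L and low CD44 after bead removal of cells carrying the B cell protein CD19. The thymus samples were lineage-negative, CD44-low thymocytes. On each array the sample was labelled with Cy3, and a common reference with Cy5, with no dye swap. The reference was a mix of 50% resting and 50% stimulated CD4 and CD8 T cells. Per the labels, the study used 13 young and 22 old mice of both sexes, and the number of mice behind each array is not stated. The spread between samples may therefore be technical in part. The p-values rest on that spread in old thymocytes alone, the only groups with replicates.

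Groups were taken from the titles of the samples, with which the source and cell type fields match; a free description field gives other groups or replicate numbers for part of the samples and was not used. There are 8 groups of age, tissue and lineage. Old CD4 and old CD8 thymocytes had 3 arrays each (replicates 4, 5 and 6), and the other 6 groups had 1 array each (replicate 4). Slide 1 held 8 arrays: the young samples, both old spleen samples and old CD4 thymocyte replicates 4 and 5. Slide 2 held 4 arrays: old CD4 thymocyte replicate 6 and the 3 old CD8 thymocyte samples.

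Per the file headers, the scans were read with Agilent Feature Extraction 11.5.1.1, and the deposited scanner files give spot and background signals as intensity, together with processed intensity values that the program corrected for background, spatial trend and dye. The deposited log ratio is the log10 of processed Cy5 over processed Cy3, per the file headers, and its sign was turned so that positive values mean more RNA in the sample. The deposited value table holds log10 values that track the log10 of the processed Cy3 intensity (r of at least 0.999 on each array), with each column's median at 1.2942; how it was made is not stated. Other deposited units per the file headers are spot counts, flags and pixel statistics, which served only as filters.

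Median spot signals were corrected with normexp (offset 50), and log ratios were normalised by loess within each array with control spots given no weight, in limma 3.58.1 under R 4.3.3 with version 1.17.8 of data.table and 2.0.0 of jsonlite. Each value is the log2 of sample over reference. Outlier spots (205 to 315 per array) were set aside, and repeated spots of a probe were averaged. The 59305 spots other than controls belong to 55681 probes, and 101 probes with a set-aside value on every spot of at least 1 array were left out. A transcript was tested if its signal was well above background in Cy3 on at least 3 arrays. The files hold no gene names: 27509 probes were matched by RefSeq identifier to 20887 symbols of assembly GRCm38.p6, and 28172 were not matched. Since the array's own build is not that assembly, no positions are given. The brightest probe stood for each gene, which left 20650 transcripts, 12949 of them with a symbol.

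Signal over background rather than read depth bounds what arrays can see: 40.3% to 48.0% of probes were well above background in Cy3, 41.8% to 49.2% in Cy5, and 0 spots were saturated. The number of arrays limits the precision. A gene not well above background on any array of a group is given a fold written "at least": its Cy3 signal in the other group, after loess and Aquantile, over the dimmest signal called well above background on each array or its own where higher. This uses Cy3 alone, is open to dye bias without a dye swap, and is not the limit of the probe itself. Where it exceeded the fold fitted to the log ratios it was no bound, and neither a fold nor a log2 difference is given.

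The 7 comparisons were contrasts of 1 limma fit of 8 group means, each the equally weighted mean of its pairs of groups: CD4 minus CD8 over 4 pairs, old CD4 minus old CD8 thymocytes, spleen minus thymus over 4 pairs, old minus young over 4 pairs, old minus young in each tissue, and the age difference in spleen minus that in thymus. The fit has 4 residual degrees of freedom, which come from the old thymocytes alone, and the 6 single arrays are assumed to vary like them. A transcript passed at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided moderated test. Unless another test is named, p-values are from this fit, and ± is its standard error (SE).

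Gene lists were written before the data were examined: CD4 lineage, CD8 lineage, double-positive thymocyte, immature single-positive thymocyte, peripheral naive T cell, memory and effector T cell, inhibitory receptors, regulatory T cell, NK and innate-like T cell, B cell, plasma cell, myeloid, erythroid, thymic stroma, adipocyte, interferon response, proliferation, cell cycle inhibitors and p53 targets, inflammatory cytokines and chemokines, immediate early, T cell receptor signalling, signalling phosphatases, migration receptors, chromatin regulators, cholesterol synthesis, glycolysis, heat shock, antioxidant and DNA repair, sex-linked, ribosomal protein, oxidative phosphorylation, and proteasome. The 30 lists with at least 5 tested members were tested with camera, which compares a list with other genes, at a preset inter-gene correlation of 0.01. No list passed camera with an estimated correlation in any of the 7 comparisons, so each list call rests on the preset. The fry test asks whether a list moves on balance without comparing it with other genes.

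The named genes follow a rule set before the data were examined: the 10 largest changes in each direction (5 for old thymocyte lineage, age in spleen and age by tissue) among those that passed with the same sign in every pair, up to 4 list members with the strongest evidence, and the genes used to check the labels. Unnamed clones and antigen receptor segments were passed over. Where nothing passed, the 5 genes with the smallest p are given.

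Each contrast was tested on simulated data with the same design, 20650 genes and 200 changed genes. It recovered 71% of 2-fold changes for lineage over 4 pairs, 40% for lineage in old thymocytes, 73% for tissue, 73% for age over 4 pairs, 42% for age in thymus, 15% for age in spleen and 1% for age by tissue. For 4-fold changes the shares were 99%, 99%, 99%, 98%, 98%, 91% and 67%, with 2 to 16 false calls. These numbers hold only as far as the single arrays vary like the old thymocytes, which the data cannot test.

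Alternatives were Agilent's log ratio, Cy3 alone scaled to its 75th percentile, the value table, no background subtraction, Aquantile, no filter or well above background on 6 arrays, the mean of a gene's probes, slide as a fixed or random block, each slide alone, an additive model, old thymocytes alone, trended robust variance, a 1.5-fold minimum, the replicate number as a block, and leaving out each array. Scaling between arrays, leaving out 3 arrays with B cell signal or both old spleen arrays, and list tests within a slide were added after the data were seen. Where a setting left a group without an array, its pair left the mean, and only the remaining pairs were compared. Slide 1 holds no old CD8 thymocytes, so age in thymus there is the CD4 pair alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.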

Results

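Gene expression was measured in 12 samples of sorted T cells, 1 array each, to follow age-related changes in T cells from the thymus to the periphery. The samples form 8 groups of age (young or old), tissue (spleen or thymus) and lineage (CD4 or CD8). CD4 cells are helper T cells and CD8 cells are cytotoxic T cells; both mature in the thymus and leave it as naive cells. Old CD4 and old CD8 thymocytes had 3 arrays each, and the other 6 groups had 1 array and no replicate. Between 40.3% and 48.0% of probes were well above background in the sample channel, and the number of arrays limits the precision. Expression is given as the log2 ratio to a common reference of resting and stimulated T cells, and 20650 transcripts were tested.

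Cd4, the coreceptor of helper cells, lay between 1.13 and 1.88 on the 6 CD4 arrays and between -1.31 and -1.05 on the 6 CD8 arrays. In old thymocytes its mean was 1.78 ± 0.10 (SD, n = 3) in CD4 cells and -1.10 ± 0.05 (SD, n = 3) in CD8 cells. Cd8a, a chain of the cytotoxic coreceptor, lay between 0.77 and 1.85 on the CD8 arrays and was lower on each CD4 array. On the CD4 arrays it ranged from -3.72 in young spleen to 0.08 in old spleen, with -1.12 and -1.69 in old thymus replicates 4 and 5 and -3.61 in replicate 6. Rag1, which cuts DNA for antigen receptor assembly, was not well above background on the 4 spleen arrays and lay between 1.95 and 4.47 on the 8 thymus arrays. Cd24a, a marker of immature thymocytes, ranged from 1.08 to 3.58 in thymus and from -1.77 to -1.43 on 3 spleen arrays, but was 1.03 in old spleen CD4. Ccr9, a homing receptor, was 3.44 in young spleen CD8 and at most 0.54 on the other spleen arrays, against 3.27 to 4.2 in thymus. S1pr1, the exit receptor, ranged from 1.26 to 2.53 in spleen and from -0.23 to 1.28 in thymus. Sell ranged from 1.33 to 1.45 in spleen and from -0.42 to 1.14 in thymus, while Klf2 overlapped widely, from 0.78 to 1.87 in spleen and from -0.48 to 1.68 in thymus.

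**Figure D1:**
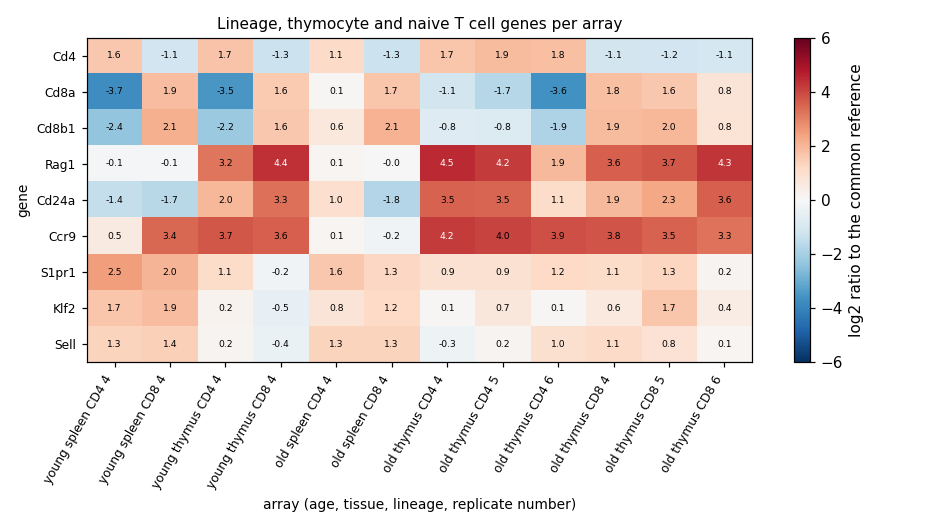
Log2 ratio to the common reference (colour and number) of 9 lineage, thymocyte and naive T cell genes (y axis) on each of the 12 arrays (x axis: age, tissue, lineage and replicate). Cd4 is at least 1.13 on each CD4 array and at most -1.05 on each CD8 array, and Cd8a is 0.08 in old spleen CD4.

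Markers of other cell types were uneven between arrays of 1 group, here given as a list's mean deviation from each gene's mean over the 12 arrays. B cell genes deviated by 1.54, 1.92 and 1.90 in old thymus CD4 replicates 4 and 5 and old thymus CD8 replicate 6, and by -1.30 to 0.29 on the other 9 arrays. In these 3 arrays Ms4a1, which encodes the B cell protein CD20, was at 4.85, 5.55 and 5.22, against at most 2.85 elsewhere. Cd19, the target of the bead removal in spleen, was at 3.17, 3.47 and 3.77 there and at most 1.30 elsewhere. Myeloid genes deviated by 2.42 in old spleen CD4 and by -0.82 to 0.57 on the other arrays; Csf1r, a macrophage receptor, was at 4 in old spleen CD4 and at most 1.53 elsewhere. NK and innate-like genes deviated by 2.19 in old spleen CD4, 0.98 in young spleen CD4 and 0.92 in young thymus CD4, against at most 0.23 on the other arrays. CD8 lineage genes deviated by 1.52 in old spleen CD4, which was sorted as CD4. Proliferation genes ranged from -1.77 in young spleen CD4 to 2.14 in young thymus CD8.

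**Figure D2:**
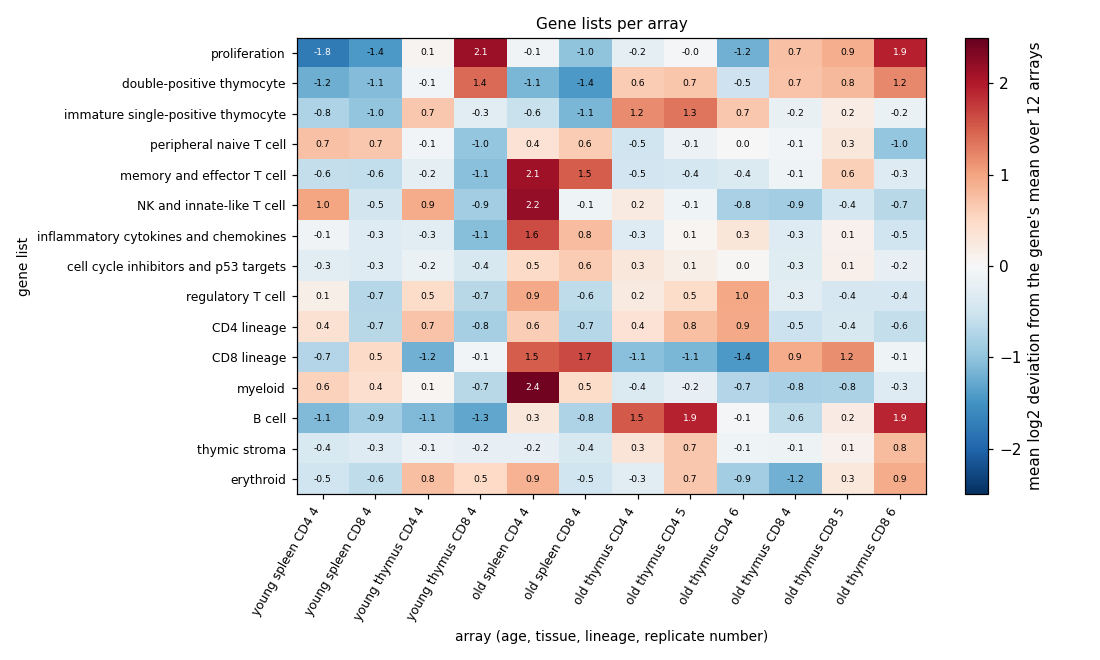
Mean log2 deviation of each gene list's members from the gene's mean over the 12 arrays (colour and number), by list (y axis) and array (x axis: age, tissue, lineage and replicate). Myeloid genes reach 2.42 in old spleen CD4, and B cell genes are at 1.54 to 1.92 in old thymus CD4 replicates 4 and 5 and old thymus CD8 replicate 6.

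Spleen against thymus compares cells sorted as naive in spleen with CD44-low thymocytes (n = 4 spleen and 8 thymus arrays). The thymocytes were not all mature: Rag1 was well above background on each thymus array. In young thymus CD8 the double-positive list deviated by 1.41 and the proliferation list by 2.14. Maturation stage and RNA of other cell types therefore enter this comparison, beside the move from thymus to spleen. Dntt, which adds bases at receptor gene joints, differed by -5.29 ± 0.60 log2 (39.1-fold lower in spleen, adjusted p = 0.00665). Smo, a hedgehog pathway receptor, was 20.8-fold lower in spleen (-4.38 ± 0.34) and Cd24a 12.2-fold lower (-3.61 ± 0.57). Rag1 (adjusted p = 0.0106) and Syt13 (adjusted p = 0.00526) were lower in spleen, where they were not well above background. Endou, Aqp11, Rapgef3, Ly6d and Marcks were 10.2- to 17.4-fold lower. Spleen cells had more S100a9 (4.54 ± 0.59 log2, 23.2-fold, adjusted p = 0.0102), S100a8 (4.34 ± 0.33, 20.2-fold) and Camp (3.5 ± 0.17, 11.3-fold). These transcripts are abundant in myeloid cells. The spread between pairs was wide, from 1.16 to 7.84 for S100a8. T cell genes higher in spleen included Dapl1 (3.89 ± 0.59, 14.8-fold), Cd55 (2.93 ± 0.44), the chemokine gene Ccl5 (2.78 ± 0.50) and the effector regulator gene Eomes (2.77 ± 0.48). Ccl5 did not pass with slide as a fixed block (2.76, adjusted p = 0.0526). Pde2a, Chil3 and Sirpb1b (at least 5.85-fold) were also higher. In total 2301 transcripts passed, 844 higher in spleen and 1457 higher in thymus, and Agilent's log ratio gave 324 and 910. A fixed block for slide gave 1411 and slide 1 alone 1490, with Dntt at -6.16 and -4.82. Without young spleen CD8 or without young thymus CD8 544 passed, without old spleen CD8 425, and without old thymus CD4 replicate 5 657. Without both old spleen arrays limma called 0, with 3608 at an unadjusted p under 0.05.

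Cell cycle genes were lower in spleen as a group. Of 33 proliferation genes 29 were lower (33 adjusted over the list alone), with a median of -1.95 log2 (camera adjusted p = 1.3e-18, adjusted p = 0.453 with an estimated correlation). Top2a, an enzyme that untangles replicating DNA, differed by -2.41 ± 0.35 and Stmn1 by -2.02 ± 0.25. The double-positive thymocyte list had 8 of 13 members lower (11 adjusted over the list alone; median -1.52, adjusted p = 2.4e-07, adjusted p = 0.363 with an estimated correlation). The immature single-positive list had 8 of 14 lower (8 lower and 1 higher adjusted over the list alone; median -1.13, adjusted p = 3.2e-06, adjusted p = 0.363 with an estimated correlation), with Ccr9 at -2.75 ± 0.14 (pairs from -3.93 to -0.15) and Sox4 at -2.75 ± 0.27. Oxidative phosphorylation genes (13 of 78 lower, 37 adjusted over the list alone, median -0.39) and proteasome genes (8 of 37 lower, 22 adjusted over the list alone, median -0.43) were shifted down (adjusted p = 5.1e-11 and 1.0e-07), each with adjusted p = 0.453 with an estimated correlation. Chromatin regulators had 7 of 32 lower (10 lower and 1 higher adjusted over the list alone), among them Ezh2 (-2.09 ± 0.28), a histone methyltransferase gene, and Satb1 (-1.42 ± 0.25). Their median was -0.29, with adjusted p = 0.00361 and adjusted p = 0.646 with an estimated correlation. With slide as a fixed block the medians were -2.28 for proliferation, -1.86 for double-positive, -1.42 for immature single-positive, -0.34 for oxidative phosphorylation, -0.47 for proteasome and -0.53 for chromatin genes. On slide 1 alone they were -1.88, -1.55, -1.21, -0.40, -0.46 and -0.39.

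Against thymus, peripheral naive T cell genes had 6 of 17 higher in spleen and 1 lower (8 higher and 2 lower adjusted over the list alone; median 1.14, adjusted p = 6.4e-05, adjusted p = 0.453 with an estimated correlation), with Ly6c1 at 2.19 ± 0.46 and S1pr1 at 1.19 ± 0.23. Memory and effector genes had 12 of 28 higher and 1 lower (18 and 3 adjusted over the list alone; median 1.02, adjusted p = 2.2e-08, adjusted p = 0.363 with an estimated correlation). Their mean deviation was 2.11 and 1.51 in old spleen CD4 and CD8. In young CD4 cells spleen was not the higher, at -0.60 against -0.25 in thymus, and in young CD8 cells the values were -0.61 and -1.05. Immediate early genes, which respond within minutes to stimulation or handling, had 7 of 23 higher (12 adjusted over the list alone; median 1.07, adjusted p = 3.0e-06, adjusted p = 0.473 with an estimated correlation), with Jun at 2.27 ± 0.30 and Fos at 2.10 ± 0.40. Myeloid genes moved with them: 10 of 18 were higher (12 adjusted over the list alone; median 0.89, adjusted p = 2.3e-11, adjusted p = 0.363 with an estimated correlation), with the lysozyme gene Lyz1 at 2.66 ± 0.22. NK and innate-like genes (5 of 13, median 0.51), CD8 lineage genes (6 of 13, median 0.69) and inflammatory cytokine genes (6 of 17, median 0.42) were higher, in each case with 1 more member adjusted over the list alone. Camera gave these 3 adjusted p = 6.4e-06, 3.1e-06 and 3.1e-06, and they had adjusted p = 0.401, adjusted p = 0.453 and adjusted p = 0.363 with an estimated correlation. Medians with slide as a fixed block were 1.18 (naive), 1.33 (memory), 0.91 (immediate early), 0.82 (myeloid), 0.39 (NK), 0.74 (CD8 lineage) and 0.57 (cytokine), and on slide 1 alone 1.32, 0.85, 0.82, 1.07, 0.68, 0.68 and 0.58. The ribosomal protein list was at 0.13 (adjusted p = 0.000749, adjusted p = 0.646 with an estimated correlation), a direction that turned with Agilent's log ratio, and was at 0.16 with slide as a block and 0.19 on slide 1. T cell receptor signalling (median -0.01), signalling phosphatase (0.03), migration receptor (0.49), cholesterol synthesis (-0.24), glycolysis (-0.07), heat shock (-0.27), thymic stroma (-0.22) and erythroid (-0.38) genes were not called as lists. With slide as a fixed block heat shock (-0.40) and thymic stroma genes (-0.36) were called lower (both camera adjusted p = 0.047). Thymic stroma genes were also called lower on slide 1 alone. The adipocyte list had 3 tested members and a median of 0.12.

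CD4 against CD8 over 4 pairs (n = 6 arrays each) asks which genes part the lineages at both ages and in both tissues. Besides Cd4 (2.77 ± 0.10 log2, 6.83-fold, adjusted p = 0.000212), CD4 cells had more of Itm2a, which encodes a membrane protein induced during thymocyte selection (2.88 ± 0.14, 7.36-fold, adjusted p = 0.000713), of the protease gene Lgmn (2.98 ± 0.32) and of the prostacyclin receptor gene Ptgir (2.78 ± 0.32). CD8 cells had more of Cd8a (-3.95 ± 0.49, 15.5-fold, adjusted p = 0.0188), Cd8b1 (-3.14 ± 0.32, 8.84-fold) and the adhesion receptor gene Adgrg5 (-3.16 ± 0.31, 8.93-fold). Further genes higher in CD4 cells were Ncmap, St8sia6 and St3gal2, at 4.96- to 6.88-fold, and Racgap1, Slc6a19, Sytl3, Ccdc102a, Ggt1, Dnajc15 and Bace1 were 2.51- to 3.5-fold higher in CD8 cells. With slide as a fixed block Slc6a19 (adjusted p = 0.0572) and Ccdc102a (adjusted p = 0.0752) did not pass. On slide 1 alone none of the genes from Racgap1 to Bace1 passed, and neither did Ptgir. The NK receptor genes Klra8 (3.12 ± 0.54, adjusted p = 0.0497), Klra4 (2.53 ± 0.30) and Klra16 (2.53 ± 0.39) were also higher on CD4 arrays. In total 265 transcripts passed, 222 higher in CD4 and 43 in CD8. A fixed block for slide gave 332 and slide 1 alone 44, with Cd4 at 2.77 and 2.73. Without young thymus CD4 or young thymus CD8 153 passed, without old spleen CD4 or old spleen CD8 98, and without old thymus CD4 replicate 5 32. Without old thymus CD8 replicate 4 105 passed, and without replicate 5 70.

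By group, regulatory T cell genes had 5 of 13 members higher in CD4 cells (9 adjusted over the list alone; median 1.07, adjusted p = 3.4e-11, adjusted p = 0.262 with an estimated correlation). Foxp3, their lineage regulator, differed by 1.92 ± 0.26, Tnfrsf4 by 2.18 ± 0.25 and Izumo1r by 1.86 ± 0.21. CD4 lineage genes had 7 of 12 higher (9 adjusted over the list alone; median 1.37, adjusted p = 2.8e-12, adjusted p = 0.262 with an estimated correlation), and CD8 lineage genes 2 of 13 lower (7 adjusted over the list alone; median -0.96, adjusted p = 3.4e-06, adjusted p = 0.372 with an estimated correlation). NK and innate-like genes had 7 of 13 higher in CD4 cells (11 higher and 1 lower adjusted over the list alone; median 1.43, adjusted p = 3.0e-11, adjusted p = 0.262 with an estimated correlation). In old thymocytes this list was not called (0 of 13 passed, median 0.27, adjusted p = 0.106), at -0.20 with slide as a block. Myeloid genes had 3 of 18 higher (12 adjusted over the list alone; median 0.78, adjusted p = 3.0e-11, adjusted p = 0.262 with an estimated correlation). The widest gap was in old spleen, at 2.42 in CD4 against 0.46 in CD8, with 0.57 against 0.42 in young spleen and 0.05 against -0.69 in young thymus; in old thymocytes the list was not called (median 0.24, -0.09 with slide as a block). Klrb1c, which encodes an NK receptor, was at 2.14 ± 0.27, with pairs from 0.26 to 3.24. Proliferation genes were lower in CD4 cells, with 1 of 33 past the threshold (1 adjusted over the list alone; median -0.88, adjusted p = 1.9e-12, adjusted p = 0.438 with an estimated correlation). The old spleen pair went the other way, at -0.09 in CD4 against -1.01 in CD8. Interferon response genes were at a median of 0.36 (1 of 29 passed, 5 adjusted over the list alone; adjusted p = 3.2e-05, adjusted p = 0.535 with an estimated correlation). Inhibitory receptor genes had a median of 0.86 (1 of 11 passed, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.000238, adjusted p = 0.372 with an estimated correlation). With slide as a fixed block the medians were 1.25 (regulatory), 1.41 (CD4 lineage), -0.89 (CD8 lineage), 1.36 (NK), 0.67 (myeloid), -1.03 (proliferation), 0.51 (interferon) and 0.98 (inhibitory). On slide 1 alone they were 1.48, 1.36, -0.76, 1.94, 0.93, -0.52, 0.39 and 0.79.

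In old thymocytes, the lineage comparison with replicates on both sides (n = 3 CD4 and 3 CD8 arrays), CD4 cells had 20.8-fold more Itm2a (4.38 ± 0.18 log2, adjusted p = 0.00057) and 10.7-fold more Ptgir (3.41 ± 0.40, adjusted p = 0.0374). They also had more Cd4 (2.88 ± 0.13, 7.37-fold), Tnfrsf4 (2.73 ± 0.31, 6.62-fold), which encodes a costimulatory receptor, and St3gal2 (2.57 ± 0.32, 5.96-fold). CD8 thymocytes had 15.1-fold more Adgrg5 (-3.92 ± 0.39, adjusted p = 0.0298), and more Atp8b4 (-1.86 ± 0.23) and Tbc1d31 (-1.64 ± 0.19). In total 37 transcripts passed, 34 higher in CD4 and 3 in CD8, where Agilent's log ratio gave 20 and 6. Slide and lineage overlapped here, as slide 1 held 2 of the CD4 and none of the CD8 arrays. With slide as a fixed block, and on slide 2 alone, the difference is CD4 replicate 6 against the 3 CD8 arrays. Both settings therefore give the same log2 values by construction and are not 2 separate checks. With slide as a fixed block 48 passed, 14 of them among the 37, and on slide 2 alone 22, 7 of them among the 37; Itm2a was at 4.19 in both. St3gal2 (adjusted p = 0.144), Atp8b4 (adjusted p = 0.137) and Tbc1d31 (adjusted p = 0.0787) did not pass with the block, and on slide 2 alone Adgrg5 (adjusted p = 0.144) did not either. Without CD4 replicates 4, 5 and 6 in turn 13, 5 and 17 passed, and without CD8 replicates 4, 5 and 6 the counts were 6, 6 and 20. Without the 3 arrays with the strongest B cell signal limma called 0, with 2196 at an unadjusted p under 0.05. Proliferation genes were lower in CD4 thymocytes as a list (median -1.80, 0 of 33 passed and 31 adjusted over the list alone; adjusted p = 3.5e-23, adjusted p = 0.476 with an estimated correlation), with a median of -2.49 both with slide as a fixed block and on slide 2. CD8 lineage genes were lower (median -1.88, 0 of 13 and 11 adjusted over the list alone; adjusted p = 4.9e-10, adjusted p = 0.476 with an estimated correlation), at -1.63 with slide as a block and on slide 2. T cell receptor signalling genes were higher (median 0.41, 1 of 25 and 4 adjusted over the list alone; adjusted p = 1.5e-06, adjusted p = 0.497 with an estimated correlation), at 0.37 with slide as a block and on slide 2.

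Age in spleen compares old with young cells sorted as naive, in a CD4 and a CD8 pair (n = 2 old and 2 young arrays). Cell composition may enter it: the old CD4 array had Cd8a at 0.08 and Csf1r at 4, against -3.72 and 1.35 in young. Cd44 was 1.88 and 2.68 log2 higher in the old arrays of the CD4 and CD8 pairs. Mouse sex may enter too and was not resolved, given the Y-linked genes below. These limits reach every comparison that uses the old spleen arrays. S100a6, which encodes a calcium-binding protein abundant in memory T cells, was 77.6-fold higher in old cells (6.28 ± 0.52 log2, adjusted p = 0.00809), by 5.66 and 6.90 in the pairs. Ccl5, a chemokine gene of effector cells, was 30.8-fold higher (4.94 ± 0.77, adjusted p = 0.037) and Plek, which encodes a kinase C substrate, 13.7-fold higher (3.77 ± 0.44, adjusted p = 0.0153). With slide as a fixed block Ccl5 did not pass (adjusted p = 0.0556). Esm1 (at least 21.3-fold) and Emp1 (at least 16.8-fold) were not well above background in young spleen. The sodium pump gene Atp1b1 was 7.16-fold lower in old cells (-2.84 ± 0.34, adjusted p = 0.0159), Xkrx 7-fold (-2.81 ± 0.29) and Ppic 8.04-fold lower (-3.01 ± 0.51). The Y-linked genes Eif2s3y (adjusted p = 0.0203) and Ddx3y (adjusted p = 0.039) passed as lower and were not well above background on either old spleen array, while Xist, transcribed from the inactive X, differed by 0.37 ± 0.58 (adjusted p = 0.934). In total 238 transcripts passed, 195 higher and 43 lower in old cells. Agilent's log ratio gave 27 and 20, Cy3 alone 74 and 49, and the value table's signals 47 and 36; Cy3 alone and these signals moved the median of all genes by -0.13 and -0.11. The count was 249 with slide as a fixed block and 414 on slide 1 alone, which held these 4 arrays; S100a6 was at 6.28 in both. Without young or old spleen CD4 31 passed, 7 higher and 24 lower, and 17 of the 238 had the opposite sign; without young or old spleen CD8 116 higher and 1 lower passed. Leaving out either array of a spleen pair leaves the other pair alone, 1 array against 1, which is a different comparison. Without old thymus CD4 replicate 4 156 passed and without old thymus CD8 replicate 4 149. Without old thymus CD4 replicate 5 limma called 0, as it did without the 3 arrays with B cell signal, where 3056 had an unadjusted p under 0.05.

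**Figure D3:**
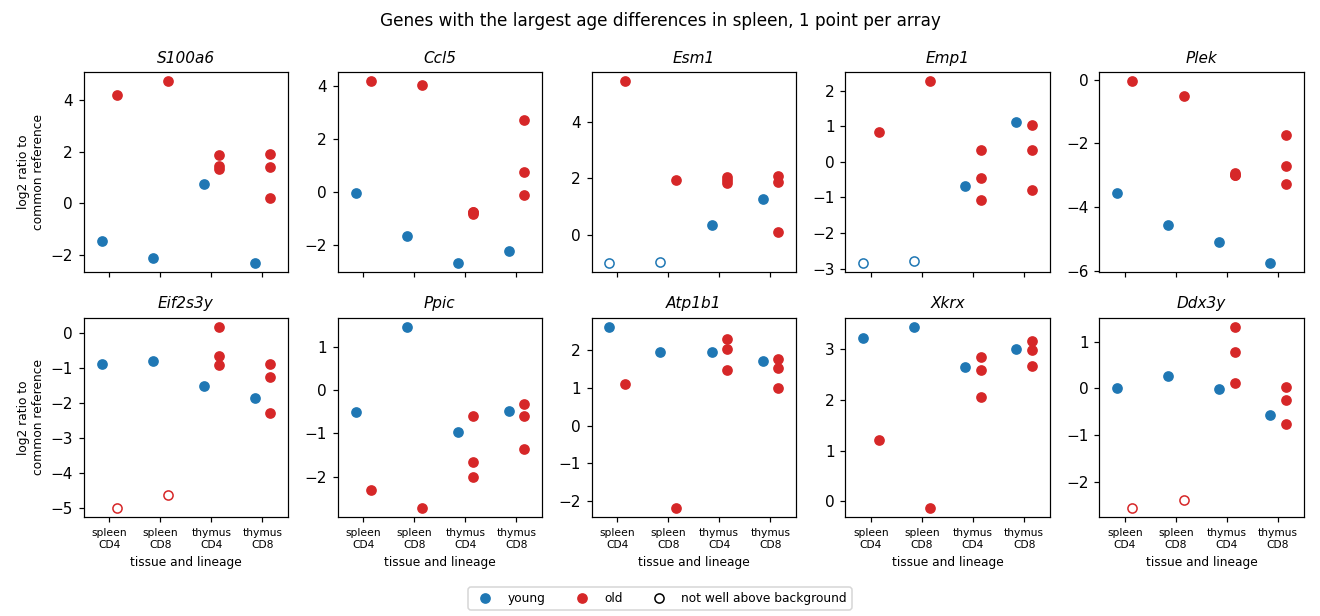
Log2 ratio to the common reference (y axis) of the 5 named genes with the largest increase and the 5 with the largest decrease in old spleen, by tissue and lineage (x axis); each point is 1 array, blue young and red old, and open points are not well above background. S100a6 is 5.66 and 6.90 log2 higher in the old arrays of the spleen pairs, and Eif2s3y and Ddx3y are not well above background in old spleen.

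Memory and effector genes were higher in old spleen as a list: 8 of 28 passed (25 adjusted over the list alone), the median was 2.27, and adjusted p = 2.0e-27, with adjusted p = 0.235 with an estimated correlation. Among them the chemokine receptor gene Ccr2 was at 3.52 ± 0.45, Anxa1 at 3.07 ± 0.41 and the integrin gene Itgb1 at 1.65 ± 0.22. CD8 lineage genes (2 of 13 higher, 8 adjusted over the list alone; median 1.53, adjusted p = 5.0e-09, adjusted p = 0.457 with an estimated correlation) moved with them, and Cd8a was 3.80 log2 higher in old than in young spleen CD4. Cell cycle inhibitors had 6 of 21 higher (10 higher and 1 lower adjusted over the list alone; median 0.49, adjusted p = 1.2e-06, adjusted p = 0.366 with an estimated correlation). These included Cdkn1a (1.84 ± 0.23, adjusted p = 0.0169) and Cdkn2a (1.92 ± 0.25, adjusted p = 0.0203), which encode p21 and p16/p19, Cdkn2b (at least 2.88-fold, not well above background in young spleen) and the p53 target Phlda3 (2.30 ± 0.32). Inflammatory cytokine genes had 5 of 17 higher (10 adjusted over the list alone; median 1.36, adjusted p = 9.7e-10, adjusted p = 0.334 with an estimated correlation), with Ccl4 at 3.30 ± 0.53 and Ccl3 at 1.86 ± 0.19. Myeloid genes had 1 of 18 higher (11 adjusted over the list alone; median 1.04, adjusted p = 9.7e-10, adjusted p = 0.366 with an estimated correlation), and without either spleen CD4 array this list's direction turned. Proliferation genes had a median of 1.04 with 0 of 33 past the threshold (0 adjusted over the list alone; adjusted p = 2.5e-09, adjusted p = 0.606 with an estimated correlation). Most of this was in the CD4 pair, from -1.77 in young to -0.09 in old cells, against -1.44 and -1.01 in the CD8 pair. Ccr9 was lower (-2.05 ± 0.22), by -3.65 in the CD8 pair and -0.44 in the CD4 pair, and did not pass in 9 of 28 alternatives (adjusted p up to 0.896). Lef1, a regulator of naive cells, did not pass (-1.53 ± 0.27, adjusted p = 0.0536); the naive list was at -0.40 and not called. Ribosomal protein genes were at -0.10 (adjusted p = 0.0235, adjusted p = 0.701 with an estimated correlation), a direction that turned with Agilent's log ratio. These medians were the same to 2 decimals with slide as a fixed block and on slide 1 alone. That holds by construction, because slide 1 held every spleen array, so it does not test slide. The naive list was called lower on slide 1 alone, though not with the block (camera adjusted p = 0.055).

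Age in thymus compares old with young thymocytes (n = 6 old and 2 young arrays). No transcript passed: limma called 0, with 862 at an unadjusted p under 0.05, and 0 with slide as a fixed block, on slide 1 alone and with either deposited processing. The smallest p-values belonged to Csprs (3.11 ± 0.38 log2, 8.65-fold higher in old, adjusted p = 0.269) and Plek (2.65 ± 0.36, 6.26-fold, adjusted p = 0.408). They were followed by Apol10b (higher in old, adjusted p = 0.421), Camp, an antimicrobial peptide gene (-1.41 ± 0.22), and Bmpr1a (at least 2.73-fold); Apol10b and Bmpr1a were not well above background on either young thymus array. Csprs was at 2.64 with slide as a block and at 2.41 on slide 1 alone. Without old thymus CD4 replicate 4 the count was 2.

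Of 30 lists 17 were called by camera. B cell genes were higher in old thymocytes (median 2.34, 0 of 15 passed and 5 adjusted over the list alone; adjusted p = 1.4e-13, adjusted p = 0.589 with an estimated correlation), with Cd74, an antigen presentation gene, at 2.81 ± 0.57 (adjusted p = 0.92). In CD4 thymocytes this list deviated by -1.10 in young and 1.54, 1.92 and -0.05 in old, the last on slide 2. In CD8 thymocytes it deviated by -1.30 in young and -0.63, 0.21 and 1.90 in old. Only old CD4 thymocytes span both slides, so a slide term takes up their uneven B cell signal. Slide 1 holds only the 2 old CD4 arrays with that signal, so neither setting tests slide for this list. Its median was 3.59 with slide as a fixed block and 3.03 on slide 1. Plasma cell genes were at 0.61 (0.88 and 1) and thymic stroma genes at 0.18 (0.20 and 0.27), and immediate early genes at 0.84 (1.34 and 0.79), with 0 members past the threshold in each (0 adjusted over the list alone). All 3 were called at adjusted p = 0.000121, 0.0116 and 5.0e-10, and had adjusted p = 0.589 with an estimated correlation. Fos was at 1.89 ± 0.50 and Jun at 1.34 ± 0.38 (both adjusted p = 0.92). Proliferation genes were lower (median -0.75, adjusted p = 5.4e-13, adjusted p = 0.589 with an estimated correlation; 0 of 33 passed, 0 adjusted over the list alone), but the median was -0.03 (adjusted p = 0.61) with slide as a block and -0.26 on slide 1. Memory and effector genes were at 0.43 (adjusted p = 0.000121, adjusted p = 0.589 with an estimated correlation; 0 of 28, 1 adjusted over the list alone), at 0.20 with slide as a block and at -0.12 on slide 1, where the opposite direction was called (adjusted p = 0.043). Naive, migration receptor, inhibitory receptor and oxidative phosphorylation genes were called at medians of 0.30, 0.24, 0.34 and -0.15, with adjusted p = 0.589 with an estimated correlation; 0 members passed, and 1 migration receptor gene did adjusted over the list alone. Their medians with slide as a block were 0.09, 0.30, -0.04 and -0.18, and on slide 1 alone -0.15, -0.17, 0.11 and -0.02, where none of these 4 was called. Slide 1 held no old CD8 thymocytes, so the values there are for CD4 thymocytes alone. Memory and effector genes deviated by -0.25 in young and -0.48, -0.43 and -0.36 in old CD4 thymocytes. In CD8 thymocytes they deviated by -1.05 in young and -0.1, 0.6 and -0.32 in old. Naive genes deviated by -0.07 against -0.49, -0.15 and 0.01 in CD4 thymocytes. In CD8 thymocytes they deviated by -0.96 against -0.06, 0.29 and -0.97.

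Old against young over 4 pairs (n = 8 old and 4 young arrays) asks which age differences run through both tissues and lineages. S100a6 was 18.5-fold higher in old cells (4.21 ± 0.34 log2, adjusted p = 0.018), though by 0.79 in 1 pair and 6.90 in another. Steadier over the pairs were Csprs (3.24 ± 0.30, 9.43-fold, adjusted p = 0.0202), from 2.65 to 3.58, and Plek (3.21 ± 0.28, 9.24-fold, adjusted p = 0.0202), from 2.12 to 4.04. Casp1 (2.97 ± 0.37, 7.82-fold) and Casp4 (2.78 ± 0.43, 6.89-fold), which encode inflammatory caspases, Ccl5 (3.78 ± 0.50, 13.8-fold), Esm1, Cxcr5, Lilrb4a and Ccl4 (4.81- to 6.73-fold) were higher too. Lower in old cells were Atp1b1 (-1.49 ± 0.22, 2.82-fold, adjusted p = 0.0459), Xkrx (-1.46 ± 0.19) and the T cell receptor adaptor gene Trat1 (-1.14 ± 0.13), and 7 further named genes from St8sia1 (-1.10) to Znrf1 (-0.86). Some pairs hardly differed, as the pairs ranged from -4.15 to -0.02 for Atp1b1, -3.59 to -0.07 for Xkrx and -2.56 to -0.09 for Trat1. For Esm1, not well above background in young spleen, the smallest pair difference was 0.08. In total 138 transcripts passed, 113 higher and 25 lower in old cells; Cy3 alone gave 36 and 16. With slide as a fixed block limma called 0 (1863 at an unadjusted p under 0.05), with S100a6 at 4.32 (adjusted p = 0.0648) and Csprs at 3 (adjusted p = 0.102); on slide 1 alone 329 passed, with S100a6 at 4.49. Without young spleen CD4, old spleen CD4, old thymus CD4 replicate 5 or both old spleen arrays the count was 0; the settings with 0 had 862 to 1863 at an unadjusted p under 0.05. Without young or old spleen CD8 34 passed, 34 of them higher, and without young thymus CD4 213 passed. Without old thymus CD4 replicate 4 31 passed and without replicate 6 76, and without old thymus CD8 replicates 4 and 5 66 and 79. Without the 3 arrays with B cell signal 5 passed.

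Memory and effector genes (5 of 28 higher, 25 adjusted over the list alone; median 1.31, adjusted p = 1.3e-24, adjusted p = 0.258 with an estimated correlation) had the smallest camera p, while the B cell list had a larger median. Inflammatory cytokine genes had 4 of 17 higher (12 adjusted over the list alone; median 0.85, adjusted p = 3.7e-11, adjusted p = 0.258 with an estimated correlation). Cell cycle inhibitors had 6 of 21 higher (10 higher and 1 lower adjusted over the list alone; median 0.38, adjusted p = 2.5e-07, adjusted p = 0.403 with an estimated correlation), with the stress gene Gadd45b at 1.58 ± 0.19 and pairs from 1.27 to 1.73. B cell genes were at a median of 1.46 (0 of 15, 4 adjusted over the list alone; adjusted p = 3.3e-07, adjusted p = 0.481 with an estimated correlation). Antioxidant and DNA repair genes had a median of 0.04 and were not called. With slide as a fixed block the medians of the 4 called lists were 1.19, 0.85, 0.43 and 2.24, and on slide 1 alone 1.45, 1.05, 0.48 and 1.43. The B cell median with the block also takes up the uneven B cell signal of old CD4 thymocytes, the only group on both slides.

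The age difference itself was tested between tissues (n = 4 spleen and 8 thymus arrays). Among named genes that passed it differed most for Camp (4.64 ± 0.35 log2, adjusted p = 0.0224), at 3.24 in spleen and -1.41 in thymus, and for Chil3 (3.91 ± 0.30, adjusted p = 0.0224), at 3.14 and -0.77; both encode proteins of granulocytes and macrophages. Ltf (3.13 ± 0.28), Lgals3 (2.87 ± 0.29) and Wfdc21 (2.82 ± 0.25) also had a more positive difference in spleen, and Cnn3 (-2.57 ± 0.27), Trib2 (-2.30 ± 0.26) and Ramp1 (-2.17 ± 0.23) a more negative one; 1 of the 2 other Ramp1 probes went the other way. The ± of these genes comes from the old thymocytes alone, and Chil3, Ltf and Wfdc21 were well above background on 5, 3 and 3 of 8 thymus arrays. It does not measure their spread between spleen samples. There the age difference of Camp was 4.83 in the CD4 pair and 1.65 in the CD8 pair, and that of Chil3 5.19 and 1.08. In total 20 transcripts passed, 16 more positive and 4 more negative in spleen. Agilent's log ratio, Cy3 alone and the value table gave 0, and a fixed block for slide and slide 1 alone also gave 0, with Camp at 4.64 (adjusted p = 0.09) and 5.19 (adjusted p = 0.0739). A random block for slide gave 16; where limma called 0 in an alternative, 684 to 2629 transcripts had an unadjusted p under 0.05. Without young or old spleen CD8 the count was 54, without young thymus CD8 12 and without old thymus CD8 replicate 6 5. Without young or old spleen CD4, young thymus CD4, old thymus CD4 replicate 4, 5 or 6, or old thymus CD8 replicate 4 or 5 it was 0. The age difference of memory and effector genes was more positive in spleen as a list (median 1.86, 0 of 28 passed and 15 adjusted over the list alone; adjusted p = 6.2e-20, adjusted p = 0.41 with an estimated correlation), at 2.07 with slide as a block and 2.31 on slide 1. So was that of proliferation genes (median 1.86, 0 of 33 and 15 adjusted over the list alone; adjusted p = 1.9e-19, adjusted p = 0.57 with an estimated correlation), at 1.16 and 1.19. Of the sex-linked list, with 3 tested members, 2 had a more negative difference in spleen adjusted over the list alone.

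Age differences correlated weakly between tissues and more strongly between lineages. Across 20650 transcripts, the difference in thymus and that in spleen had a Pearson r of 0.288 and a Spearman rho of 0.165, and of the 238 transcripts that passed in spleen 161 had the same sign in thymus. Between CD4 and CD8 cells r was 0.531 and rho 0.402. These 2 correlations are across genes, which are not independent replicates.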

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

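The tests of neutrophil RNA and of slide were chosen after the result was seen.

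The age difference differed between spleen and thymus in 20 transcripts, by a test of that difference whose error comes from the old thymocytes alone. It was more positive in spleen for Camp (4.64 log2), Chil3 (3.91), Ltf (3.13), Lgals3 (2.87) and Wfdc21 (2.82), and more negative for Cnn3 (-2.57), Trib2 (-2.30) and Ramp1 (-2.17). The age differences of Cnn3, Trib2 and Ramp1 were -3.35, -3.23 and -3.53 in the spleen CD8 pair and -1.60, -1.69 and -0.93 in the CD4 pair, each pair being 1 array against 1; no explanation was tested for them.

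The 16 transcripts with a more positive difference in spleen include 8 of a list of 28 neutrophil genes. Slide as the whole source is argued against for spleen and CD4 thymocytes only: the median of the 16 was 2.99 log2 on slide 1 alone and 2.55 on all arrays. Slide 1 holds every spleen array, so the spleen part is the same by construction. It holds no old CD8 thymocytes, so slide was not tested for CD8 thymocytes. No transcript passed on slide 1 alone or with slide as a fixed block, where the median was 2.59. RNA of neutrophils may contribute, since 13 tested neutrophil genes outside the 16 had a median of 1.17 (median absolute deviation 1.7), with 11 of 13 positive, while Csf3r was at 0.03 and Itgam at -0.43. For S100a8 (4.84) and S100a9 (4.61) much of the difference was a lower value in old thymus (-2.62 and -3.04), and the difference in spleen did not pass (2.22, adjusted p = 0.133, and 1.57, adjusted p = 0.678). The median age difference of the called genes was 3.45 in the spleen CD4 pair and 0.69 in the CD8 pair, and 14 myeloid genes outside the neutrophil list were at 2.16 and -0.11; the sorts for T cells would be meant to remove such cells. A change of these genes with age within T cells stays open and untested.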

How the results depend on the processing

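The settings without 3 arrays with B cell signal, without both old spleen arrays, with scaling between arrays, and the list tests within a slide were chosen after the data were seen. Aquantile leaves log ratios as they are by construction. Probes below background, more than 50% on each array, bound what any setting can see, and folds of genes near background are uncertain.

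Counts are given in the order lineage, lineage in old thymocytes, tissue, age, age in spleen and age by tissue. Those more than 1.5 times off were, with Agilent's log ratio, 86 (lineage), 1234, 24, 47 and 0 (tissue to age by tissue); with Cy3 alone 60 (lineage in old thymocytes), 52, 123 and 0 (the 3 age counts); with the deposited value table, 156, 57, 1436, 22, 83 and 0. Without background subtraction lineage in old thymocytes gave 57 and age by tissue 10; well above background on 6 arrays gave 5 for age by tissue. Slide as a fixed block gave 1411 for tissue and 0 for age and for age by tissue, where the median SE over all transcripts went from 0.15 to 0.17 and from 0.30 to 0.34 log2 with 1 residual degree of freedom fewer, while S100a6 for age stayed near its 4.21, at 4.32. Slide 1 alone gave 44 (lineage), 1490, 329, 414 and 0 (tissue to age by tissue), and slide 2 alone 22 for lineage in old thymocytes, with fewer arrays by construction. Trended robust variance gave 44 for age and 0 for age by tissue. The additive model gave 825 for lineage, 25 for age and 0 for age in spleen and age by tissue. Without the 3 arrays with B cell signal old thymocyte lineage, age in spleen and age by tissue gave 0 and age 5. Without both old spleen arrays lineage gave 98, and tissue and age 0. Where limma called 0, 684 to 3608 transcripts had an unadjusted p under 0.05. Unless construction shows it, the cause was not tested. Apart from leaving out 1 array and the replicate block, given below, the other settings stayed within 1.5 times of these counts.

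With each array left out in turn, the counts ranged from 32 to 308 for lineage, 5 to 37 for lineage in old thymocytes, 425 to 2474 for tissue, 0 to 213 for age, 0 to 2 for age in thymus, 0 to 249 for age in spleen and 0 to 54 for age by tissue. Lists called ranged from 14 to 23, 12 to 18, 15 to 18, 14 to 18, 14 to 21, 10 to 20 and 12 to 18. Where the array left out had no replicate its pair left the mean, so these ranges also hold changes of the pairs compared.

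With the replicate number as a block, for a possible pairing of samples, the counts were 11, 6, 15, 0, 0 and 0 (0 for age in thymus). Deviations of same-numbered CD4 and CD8 samples correlated at -0.259, 0.0902 and -0.475, so the values show no pairing. They cannot exclude one, because slide and the uneven B cell signal also enter these deviations. The block leaves fewer residual degrees of freedom by construction.

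Of 30 lists, camera with an estimated correlation called 0 in each comparison, and fry 5, 1, 8, 1, 0, 1 and 0 for lineage, old thymocyte lineage, tissue, age, age in thymus, age in spleen and age by tissue; slide 1 alone called 22 for age by tissue. Apart from these tests, 108 called lists were the same in 1945 of 2101 alternatives, lost the call in 134, and turned direction uncalled in 21. Memory and effector genes in thymus turned direction with a call on slide 1 alone (adjusted p = 0.043). Slide 1 holds no old CD8 thymocytes, so age in thymus there is the CD4 pair alone, a different comparison. The list's mean deviation was -0.25 in young and -0.48, -0.43 and -0.36 in old CD4 thymocytes, the last on slide 2. In CD8 thymocytes it was -1.05 in young and -0.1, 0.6 and -0.32 in old. Old CD4 thymocytes from both slides were thus lower than the young CD4 array, which was on slide 1. Old CD8 thymocytes, all on slide 2, were higher than the young CD8 array on slide 1. Age and slide cannot be told apart for these CD8 samples. For 203 results of a named gene in a comparison where it passed, 1550 of 2436 values without 1 array and 2354 of 3401 other values kept direction and call. Il1b turned to -0.01 for lineage without old spleen CD4, old spleen CD8 or both, and to -0.09 for age and -0.38 for age in spleen without young or old spleen CD4; with 1 array left out it ranged from -0.01 to 1.35, -0.09 to 1.26 and -0.38 to 3.69. Without both old spleen arrays Ccr2 (-0.05), Ddx3y (0.43) and Eif2s3y (0.83) turned for tissue, and Ccr9 (0.11) for age. The cause was not tested. Age correlations across genes kept their sign in each alternative.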

Other observations

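The 4 counts of other splits were planned; the tests on memory cells, CD8 cells, signal and mouse sex were chosen after the result was seen.

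Stromal genes went with the B cell genes in old thymocytes. Krt18, a keratin gene of epithelium, was at 2.66, 3.41 and 2.28 in old thymus CD4 replicates 4 and 5 and old thymus CD8 replicate 6, and at most 1.21 elsewhere. Dcn, a connective tissue gene, was at 1.58, 2.08 and 4.10 there and at most 1.18 elsewhere. Mki67, a marker of dividing cells, ranged from -4.46 in young spleen CD4 to -0.71 in old spleen CD4, and from -3.12 in old thymus CD4 replicate 6 to 2 in old thymus CD8 replicate 6. Hbb-bs, a globin gene, ranged from -0.11 to 3.17. These genes were chosen after their values were seen.

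Memory and effector genes were higher in old spleen, with a median of 2.27 log2 over 28 genes. CD8 cells in the old CD4 sample are argued against as the whole source: the CD8 pair alone had a median of 1.44, with 27 of 28 genes higher, beside 2.84 in the CD4 pair; 6 of the 28 genes are also CD8 lineage genes. Memory cells carried through the sort may contribute, since Cd44, whose protein set the gate, was 1.88 log2 higher in old cells of the CD4 pair and 2.68 higher in the CD8 pair. Higher overall signal on the old spleen arrays was not decided by the largest median of the ribosomal protein, proteasome and oxidative phosphorylation lists, 0.24, because each array's log ratios were centred. A change with age within naive cells stays open and untested: Sell was at -0.06, Ccr7 at -0.62 and Lef1 at -1.53, and 11 of 17 naive genes were lower.

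The Y-linked genes Eif2s3y (-5.00 and -4.63) and Ddx3y (-2.56 and -2.38) were lower on both old spleen arrays than on the other 10 arrays (-2.28 to 0.19 and -0.76 to 1.32). Loss of signal is argued against, as 41.9% of probes or more were well above background on these arrays, beside 40.3% and 43.1% on the young spleen arrays. RNA from female mice alone could give such values and cannot be told apart from other sources, because Xist differed from the mean of the other arrays by 0.09 log2, within their SD of 0.81. That SD includes old thymus CD4 replicate 4, with Xist at -3.59 and not well above background. A difference in mouse sex may thus enter the age comparison in spleen, which was not resolved. Both Y-linked genes were well above background on each old thymus array (-2.28 to 0.19 and -0.76 to 1.32). This argues against a loss of their expression with age in thymocytes. A loss confined to spleen cells stays open and untested.

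Splits of the samples within the other factors gave as many transcripts as the real one in 1 of 80 for lineage (265, highest other 32) and 1 of 64 for tissue (2301, highest other 247). These shares alone do not exclude chance, because the residual spread comes from the old thymocytes. A split that moves an array of another lineage or tissue into those groups widens that spread by construction. For lineage in old thymocytes the 10 splits are too few for a share under 5% (37, highest other 2). For age over 4 pairs, 5 of 64 gave as many as the real 138, up to 291, so chance was not excluded. In 4 of these 5 the labels of both spleen pairs were swapped together, which keeps the old spleen arrays apart from the young ones. With 1 spleen pair swapped the highest count was 98. What drives these counts was not tested.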
